A study of Gallus gallus with 15 samples.

How the data were processed

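Total RNA of 4 populations sorted from chicken spleen was measured on 15 arrays, 4 each of putative conventional dendritic cells (cDC), the macrophage population (MP) and T cells and 3 of B cells, without replicate 3. Per the labels' protocols, the spleens were pressed through a mesh, digested with collagenase D and DNase and spun on a density gradient before sorting. Per the labels' protocols, 50 ng of RNA per sample was amplified and labelled with Cy3 for hybridisation to 1 array. Per the file headers, the arrays have a custom Agilent chicken design built on genome galGal3 and were read with Feature Extraction 10.10.1.1 under a one-colour protocol. Per the file headers, the scanner software subtracted background and removed spatial and multiplicative trends within each array to give a processed intensity, with surrogate values for spots not above background and no adjustment between arrays. The other columns used hold the raw mean intensity and the median local background of each spot, per the file headers. The authors' deposited table holds log2 values whose distributions are nearly equal between arrays (medians 5.92 to 5.94), as quantile normalization gives. Per the submitters' processing notes, limma and R 2.15.0 were used, and the order, settings and background step are not stated in the sources used here. The rank correlation of the authors' log2 values with the raw mean intensity of the same array was 0.979 to 0.988.

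Each array had 60892 spots that were not controls, for 44948 probes. Control spots were left out, as were 350 to 675 flagged spots per array, and 0 spots were saturated. The 75th percentile of the processed intensity was 337 to 625 per array, and 68.5 to 77.7% of probes were well above background by the scanner's own test, which bounds how dim a transcript can be measured. The number of arrays limits the precision.

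Spots of a probe were averaged, and log2 processed intensities were scaled by subtracting each array's 75th percentile. A probe was kept when well above background on at least 3 arrays, the size of the smallest group, which removed 9903 probes, and 66 with a missing value were dropped. Names were taken from current symbols for 12978 probes, through an accession for 11466, through a gene identifier for 906 and through a synonym for 450, while 3715 kept the array's own name. Another 14391 probes carry an accession alone and 230 no name, and these were tested as unnamed probes. Of the rest, 798 are named by a human or mouse transcript, 13 are copies within the array design and 1, for FLT3, was named from the description column after the data were seen. For a gene with several probes the probe with the highest mean over all arrays was used. Of 7005 genes with several measured probes, between 20 and 150 had probes called in opposite directions, depending on the comparison. In all, 11539 genes and 10632 unnamed probes were tested, and the unnamed probes called numbered 4573 for cDC against MP, 5920 for cDC against B, 6853 for cDC against T, 6144 for MP against B, 6970 for MP against T and 3913 for B against T.

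A linear model over all 15 arrays with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3 (11 residual and 2.224 prior degrees of freedom), and moderated two-sided tests were made for the 6 pairs of groups. P-values were adjusted by Benjamini and Hochberg within each pair over genes and unnamed probes, and a gene was called at an adjusted p under 0.05. A gene counted as specific to a population when called and at least 2-fold higher there than in each of the other 3, and as shared by a pair when this held for both members against both other populations. Overlaps of shared sets were set beside the number that independent lists of the same sizes would share and beside 20 simulations with unchanged groups, which gave 0 shared genes. With no group changed, 0 was near certain, so these simulations do not weigh the effect of the shared arrays. Because the groups of 3 or 4 arrays were too small to divide, each pair was compared with the same other arrays. Where a gene was below background on every array of the lower group, the fold is given as a bound from the dimmest level well above background, in the words "at least". Tables were handled with the data.table package (1.17.8), pandas 2.3.3 and NumPy 2.4.6 in Python 3.11.15, and figures were drawn with matplotlib 3.10.9.

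The 32 lists of at least 5 measured members covered conventional, XCR1-type, CD11b-type, mature or migrating and plasmacytoid dendritic cells, dendritic cell transcription factors, macrophage core, red pulp macrophages and iron handling, B cells, plasma cells, T cells, natural killer and cytotoxic cells, thrombocytes, erythroid cells, heterophils and granulocytes, stroma and endothelium, MHC class II and class I presentation, phagocytosis and lysosome, complement and opsonin receptors, pattern recognition receptors, chemokine and cytokine receptors, chemokines and cytokines, interferon-stimulated genes, cell cycle, early response and dissociation stress, cytosolic ribosomal proteins, mitochondrial oxidative phosphorylation, glycolysis, cholesterol synthesis, antigen receptor signalling, and actin and migration. The sort antigens formed a further list, with 5 measured members, that was not tested. Members come from mammalian and avian background knowledge and some stand in several lists. Each list was tested with camera of limma at a preset correlation of 0.01 and adjusted over the 32 lists, and again with a correlation estimated per list.

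Genes were named by a rule. It took, per pair of populations, the 10 called genes with the largest fold change in each direction that were well above background on every array of the higher group and did not overlap between groups, and the 10 leading genes of each set. It added all sort antigen genes, up to 4 members of each described list with the largest change, and FLT3, XCR1, ZBTB46, CSF1R, IRF8, BATF3, ID2, CADM1, CD14, TLR3, TLR4, PAX5 and BCL11B. The text prints a part of these genes. The fit was tested on simulated data with 200 changed genes among 11539, where it recovered 78 to 80% of 2-fold and 92 to 94% of 4-fold changes, with 3.91 to 4.97% false calls. It recovered 46 of 50 genes raised 4-fold in cDC alone, and camera called 0 of 32 lists when none was changed. The simulated genes varied independently, whereas correlations estimated per list in the data reached 0.553. The simulation therefore cannot tell how often camera calls unchanged lists in the real data.

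Alternatives were quantile normalization, normexp background correction with an offset of 50, the authors' deposited log2 values, no filter on dim probes, a stricter filter, the mean of a gene's probes, slide as a block, each slide alone, the replicate number as a block, array weights, only the arrays of the compared groups, leaving out each array in turn, and camera with an estimated correlation. Camera with an estimated correlation and slide as a block was added after the data were seen. Replicates 1 and 2 of each group are on slide 1 and replicates 3 and 4 on slide 2, and 1 scan time was found per slide. The replicate numbers were taken to pair the samples of cDC and MP (correlations of residuals 0.138 to 0.410 over 4 pairs) and of B and T cells (0.177 to 0.316 over 3 pairs), since every pair exceeded 0.1. This rests on the data alone, and other numbers on the same slide correlated by -0.0199 to 0.253 and -0.0831 to 0.161. In the other comparisons the samples share a number and a slide, and not every pair exceeded 0.1. The assignment of animals to replicates is not given in the sources used here. Probes for the 8F2 and KUL01 antigens and Bu-1 were not found by name, and fry and tests of single splice forms were not run.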

Results

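RNA of 4 sorted cell populations from the spleens of histocompatible female chickens was measured on 15 one-colour Agilent arrays, which report transcript abundance as fluorescence intensity. The putative conventional dendritic cells (cDC, 4 arrays) carried MHC class II and the antigen of 8F2, an antibody to putative chicken CD11c, and lacked KUL01, Bu-1 and CD3. The macrophage population (MP, 4 arrays) was sorted on KUL01, an antibody to chicken mononuclear phagocytes. B cells (3 arrays) were sorted on Bu-1, a chicken B-cell antigen, and T cells (4 arrays) on CD3, the signalling part of the T-cell receptor. The labels give 4 chickens, and RNA of different spleen pools was mixed where a sort gave under 50 ng. A replicate therefore need not be 1 animal, and the p-values measure the spread between these samples. Per array, 68.5 to 77.7% of the 44948 probes were well above background, and the 75th percentile of the signal was 337 to 625 intensity units. The number of arrays limits the precision.

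The series title asks whether conventional dendritic cells exist in the chicken, a question addressed by setting the cDC beside the macrophage population and the lymphocytes. Expression profiles of cDC were nearest to those of MP, with a distance (1 minus Pearson's correlation across 11539 genes) of 0.0678 ± 0.00434 (SD over 16 array pairs). From cDC to B cells the distance was 0.0944 ± 0.00798 (12 pairs) and from cDC to T cells 0.121 ± 0.0113 (16 pairs). MP lay 0.11 ± 0.0105 from B cells and 0.13 ± 0.0133 from T cells, and B and T cells lay 0.0656 ± 0.00463 apart. Within a population the mean distance was 0.0094 for cDC, 0.0155 for MP, 0.0134 for B cells and 0.0106 for T cells, so every distance between populations exceeded those between replicates. Genes are not independent replicates, and these distances carry no test. Without a filter on dim probes the distance of cDC to MP was 0.0422, over 1.5 times lower, and cDC remained nearer to MP than to the lymphocytes under each setting tried.

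**Figure D1:**
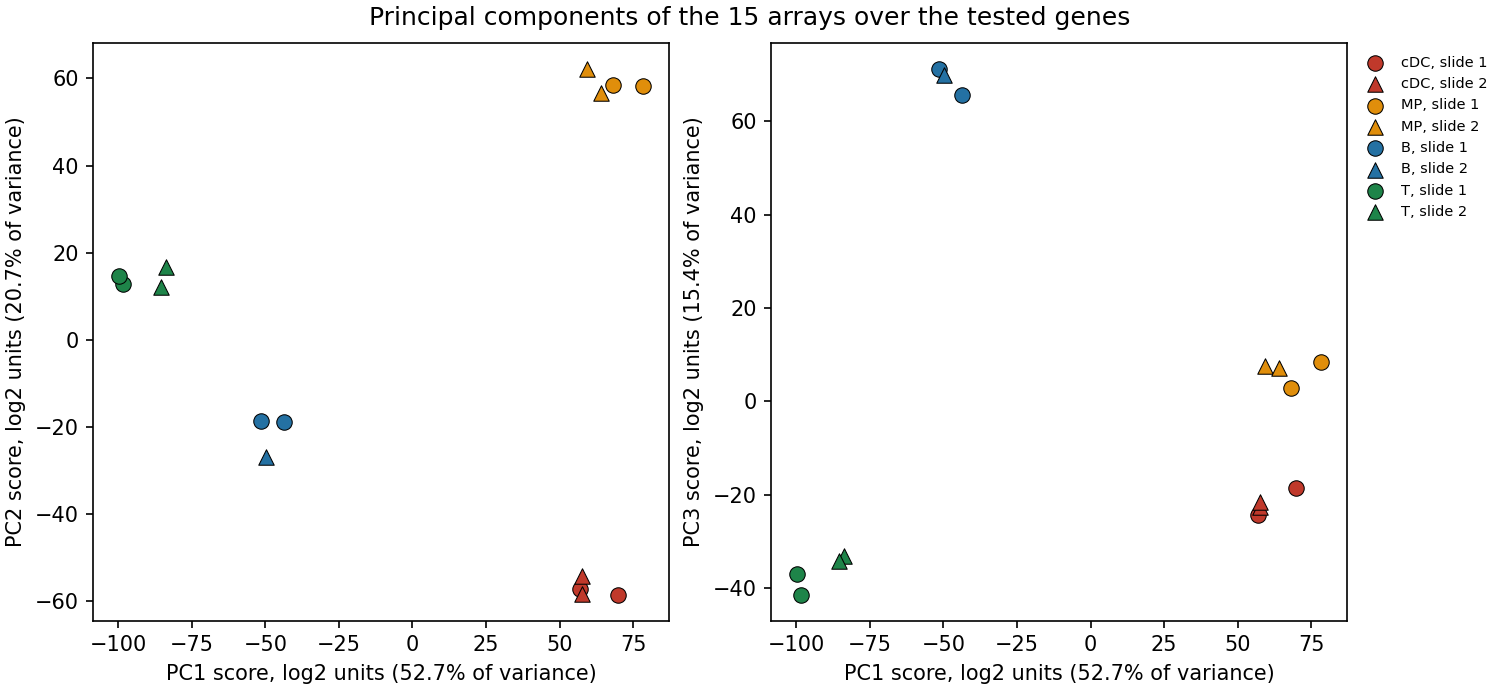
Scores of the 15 arrays on the first 2 principal components of the log2 normalised intensities, 1 point per array coloured by population. The first component (52.7% of the variance) separates cDC and MP, at 57.0 to 78.4, from B and T cells, at -99.6 to -43.6, and the second (20.7%) separates cDC from MP.

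Transcripts of the sorting antigens followed the sorts for CD3 and MHC class II. CD3E, a chain of the CD3 complex, had a mean log2 normalised intensity of 8.16 ± 0.046 (SD, n = 4) in T cells, 5.25 ± 0.40 (n = 4) in MP, 4.65 ± 0.26 (n = 3) in B cells and 3.31 ± 0.67 (n = 4) in cDC. The other CD3 chains, CD3D and CD247, were also lowest in cDC, at 5.57 ± 0.51 and 1.62 ± 0.74, against 9.46 ± 0.055 and 6.94 ± 0.051 in T cells. BLB1 and BLB2, the MHC class II beta chains, are near-identical paralogs whose probes may read each other. BLB2 was at 9.73 ± 0.31 in cDC, 9.95 ± 0.34 in MP, 9.14 ± 0.12 in B cells and 6.73 ± 0.67 in T cells, and BLB1 at 8.82 ± 0.13, 8.27 ± 0.094, 6.61 ± 0.20 and 3.70 ± 0.76. The genes of Bu-1, of the KUL01 antigen and of CD11c had no match among the gene names of the array, so those sorts could not be checked. Intensities are log2 units above the 75th percentile of each array.

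**Figure D2:**
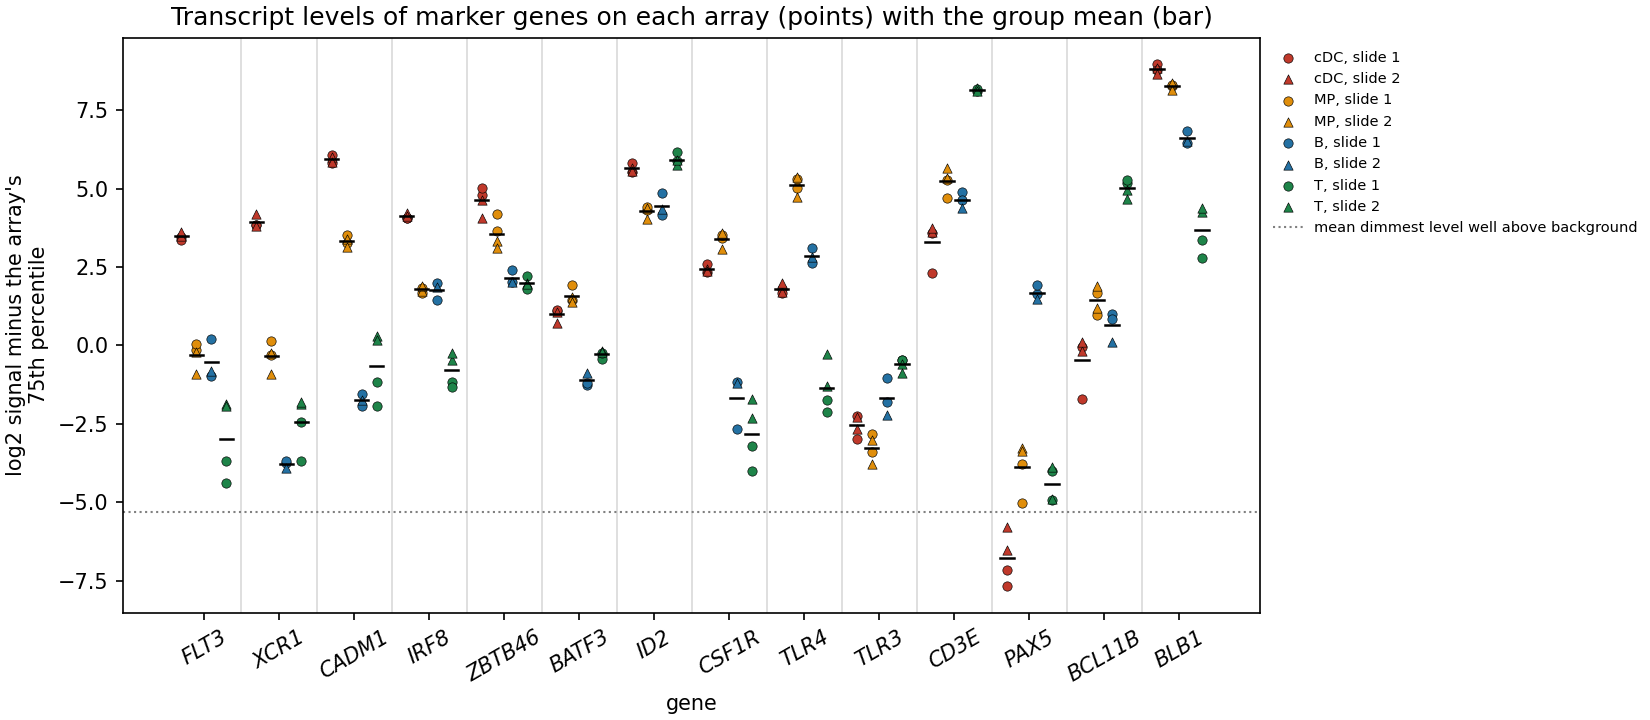
Log2 normalised intensity (log2 units above the array's 75th percentile) of selected genes, with 1 point per array (circles for slide 1 and triangles for slide 2), a bar at the mean of each population (4 arrays of cDC, MP and T, 3 of B) and a dotted line at the mean dimmest level well above background. FLT3, XCR1 and IRF8 were highest in cDC, at means of 3.49, 3.92 and 4.12.

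All 6 pairs of populations were compared with limma, and a gene was called at an adjusted p under 0.05. Each ± beside a log2 fold change is its standard error. Gene lists were fixed before the data were examined, as were the model, the threshold and the rule for naming genes. Coordinates are probe positions on build galGal3 as the array's annotation gives them, and exons were not annotated. The median log2 fold change over all genes was 0.077 for cDC minus MP, -0.12 for cDC minus B, -0.11 for cDC minus T, -0.19 for MP minus B, -0.22 for MP minus T and 0.00 for B minus T. With normexp background correction it was -0.073 for MP minus B and -0.075 for MP minus T. List medians against B and T cells are given relative to the median gene of the comparison where stated. Both slides held arrays of every population, and adding slide as a block left the fold changes between cDC, MP and T cells as they were.

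Several genes known from mammalian dendritic cells were higher in cDC than in MP (n = 4 against 4). XCR1, the chemokine receptor of cross-presenting dendritic cells, was higher by a log2 fold change of 4.25 ± 0.34 (adjusted p = 4.02e-07; chromosome 2, 42746968 to 42747027). FLT3, the receptor for the growth factor on which dendritic cells depend, was higher by 3.79 ± 0.49 (adjusted p = 2.66e-05; chromosome 1, 180345806 to 180345865). Its probe carries only a transcript identifier, and its name comes from the description column. CADM1, an adhesion molecule of XCR1-positive dendritic cells, and IRF8, a transcription factor they require, were higher by 2.61 ± 0.38 and 2.33 ± 0.21 (adjusted p = 7.61e-05 and 9.92e-07). ZBTB46, a transcription factor of conventional dendritic cells (chromosome 20, 9577342 to 9577401), rose by 1.06 ± 0.23 (adjusted p = 0.00201), although its cDC and MP arrays overlapped. ID2, another regulator of these cells, rose by 1.35 ± 0.15 (adjusted p = 6.89e-06). BATF3, which acts with IRF8 in mammals, was lower in cDC, at -0.56 ± 0.14 (adjusted p = 0.00409). TLR3, a sensor of double-stranded RNA, was higher by 0.71 ± 0.26 (adjusted p = 0.0397), at low levels in both populations and with overlapping arrays. The call of TLR3 ended on slide 1 (0.49) and slide 2 (0.92) alone, without a filter on dim probes, with normexp (0.20) and without cDC replicate 2 (0.61), 3 (0.75) or 4 (0.62) or MP replicate 1 (0.66) or 4 (0.53), while that of BATF3 ended on slide 1 alone (-0.55). For the other genes named as higher or lower in a comparison, the arrays of its populations did not overlap.

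Of the conventional dendritic cell core list, 15 of 29 measured members were higher in cDC, 5 lower and 9 not called (16 higher and 5 lower adjusted over the list alone). The median was 0.68 (0.51 on slide 1 and 0.83 on slide 2). SNX22, a sorting nexin, rose by 3.74 ± 0.25, while DPP4, a surface peptidase, was at least 44.4-fold lower (adjusted p = 2.09e-07). The list passed camera (adjusted p = 0.0482) but not with slide (adjusted p = 0.0595) or the replicate number (adjusted p = 0.0727) as a block, and its adjusted p = 0.314 with an estimated correlation. Of the XCR1-type list, 10 of 19 were higher, 6 lower and 3 not called (11 and 6 adjusted over the list alone). It had a median of 0.71 (0.53 and 0.79 on the slides), adjusted p = 0.306 in camera and adjusted p = 0.642 with an estimated correlation. DNASE1L3, an extracellular DNase, was among its higher members, at 3.38 ± 0.38. Of the CD11b-type list, 2 of 11 were higher and 6 lower in cDC, with 3 not called (also 2 and 6 adjusted over the list alone). SIRPA, an inhibitory receptor, ZEB2, a transcription factor, and CX3CR1, a chemokine receptor, were lower, at -2.50 ± 0.21, -2.25 ± 0.31 and -2.14 ± 0.27. Its median was -0.79 (-0.90 and -0.68 on the slides), with adjusted p = 0.044 in camera, adjusted p = 0.0591 with slide as a block, adjusted p = 0.0562 with the replicate number as a block and adjusted p = 0.314 with an estimated correlation.

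Macrophage genes were lower in cDC than in MP. FN1, fibronectin, had a log2 fold change of -7.24 ± 0.44 and CD36, a scavenger receptor, of -6.16 ± 0.34 (adjusted p = 3.15e-08 and 1.11e-08). TLR4, the lipopolysaccharide receptor, was at -3.32 ± 0.30, and CD14, its co-receptor, was at least 3.55-fold lower (adjusted p = 1.24e-06 and 3.21e-05). CSF1R, the receptor for the macrophage growth factor, was at 2.44 ± 0.11 (SD) in cDC and 3.40 ± 0.22 in MP, a difference of -0.96 ± 0.43 that missed the threshold (adjusted p = 0.0792). CSF1R was called lower in cDC when only the cDC and MP arrays were fitted (adjusted p = 0.000555), with normexp (0.00333), the authors' values (0.0305), the mean of its probes (0.044) or array weights (0.0348), and without B replicate 2 (0.0467), T replicate 2 (0.0356) or T replicate 3 (0.0438), with adjusted p up to 0.182 (slide 1 alone) over the alternatives. Of the macrophage core list, 32 of 42 members were lower in cDC, 2 higher and 8 not called (33 and 2 adjusted over the list alone). Its median was -1.51 (-1.42 and -1.67 on the slides), its adjusted p = 2.36e-11 in camera and adjusted p = 0.272 with an estimated correlation.

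Complement and opsonin receptors, the proteins that tag and bind particles for uptake, were lower in cDC for 12 of 22 members, higher for 2 and not called for 8 (13 lower and 4 higher adjusted over the list alone). GAS6, a bridge to dying cells, was at least 109-fold lower, C1QB, a chain of C1q, was at -4.80 ± 0.38, and AXL (listed on the array as TYRO3), a receptor of GAS6, at -4.42 ± 0.28. The median was -1.30 (-1.33 and -1.36 on the slides), with adjusted p = 0.000584 in camera and adjusted p = 0.272 with an estimated correlation. Phagocytosis and lysosome genes were lower for 25 of 45 members, higher for 5 and not called for 15 (as adjusted over the list alone). Among them were the cathepsins CTSD and CTSK at -3.73 ± 0.33 and -3.28 ± 0.20. ATP6V0D2, a subunit of the proton pump, was at least 20.2-fold lower. The list's median was -0.63 (-0.61 and -0.57 on the slides), adjusted p = 4.47e-05 in camera and adjusted p = 0.272 with an estimated correlation. Of the pattern recognition receptors, 12 of 26 were lower, 3 higher and 11 not called (as adjusted over the list alone). They included TLR1B (listed as TLR6) at -4.33 ± 0.12 and TLR2 (listed as TLR2-2) at -3.83 ± 0.18. TLR21 was at -5.78 ± 0.22 on its brightest probe, and probes named for it were called in opposite directions. This list's median was -0.081 and its mean -1.04 (medians -0.27 and -0.0073 on the slides), with adjusted p = 0.0107 in camera and adjusted p = 0.303 with an estimated correlation.

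Genes of DNA replication and mitosis were higher in cDC for 40 of 42 measured members, lower for 0 and not called for 2 (as adjusted over the list alone). TPX2, a spindle protein, RRM2, which makes deoxynucleotides, and KIF11, a mitotic motor, rose by 1.48 ± 0.12, 1.46 ± 0.13 and 1.42 ± 0.13, and MKI67, the Ki-67 antigen, by 1.36 ± 0.20 (adjusted p = 7.64e-05). The list's median was 0.90 (0.91 on slide 1 and 0.95 on slide 2), adjusted p = 2.36e-11 in camera and adjusted p = 0.272 with an estimated correlation. Subunits of the mitochondrial respiratory chain were higher for 24 of 50, lower for 3 and not called for 23 (25 and 3 adjusted over the list alone). UQCRQ was at 1.52 ± 0.16 and NDUFS4 at 0.98 ± 0.08. Their median was 0.25 (0.31 and 0.20 on the slides), adjusted p = 0.00206 in camera and adjusted p = 0.546 with an estimated correlation. Genes of MHC class II presentation went both ways, 8 of 20 higher, 7 lower and 5 not called (as adjusted over the list alone). CIITA, the master regulator of class II genes, rose by 1.85 ± 0.16, and the proteases LGMN and CTSH were lower, at -1.46 ± 0.18 and -1.26 ± 0.15. The median was -0.21 (0.0057 and -0.32 on the slides) with adjusted p = 0.599 in camera.

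The lists of other cell types differed in how they stood between cDC and MP. Of the T-cell list, 27 of 34 members were lower in cDC, 4 higher and 3 not called (as adjusted over the list alone). The T-cell receptor alpha chain (TRA@) was at -2.71 ± 0.39, CD8BP (listed as CD8B) at -2.47 ± 0.44 and CD3E at -1.94 ± 0.28. CD2, an adhesion molecule of T cells, went the other way and was at least 9.99-fold higher in cDC (adjusted p = 9.01e-06). The list's median was -1.56 (-1.82 and -1.44 on the slides), adjusted p = 1.64e-06 in camera and adjusted p = 0.314 with an estimated correlation. Of the natural killer and cytotoxic list, 10 of 22 were lower and 1 higher (median -0.93, adjusted p = 0.00663), with GZMA, a granzyme, at -3.04 ± 0.26. Of the thrombocyte list, 9 of 15 were lower and 2 higher (median -1.16, adjusted p = 0.00396), with P-selectin (SELP) at -3.63 ± 0.27. Of the heterophil and granulocyte list, 4 of 14 were lower and 1 higher (median -0.52, adjusted p = 0.0205), with EXFABP (listed as P20K) at -7.26 ± 0.46 and MMP9 at -5.52 ± 0.52. Of the stromal and endothelial list, 8 of 18 were lower and 1 higher (median -1.47, or -1.25 with members below background at their bound, adjusted p = 0.0107). ACTA2, smooth muscle actin, was at -3.47 ± 0.30. Adjusted over the list alone, each of these 4 lists gave the same counts. With an estimated correlation they had adjusted p = 0.272, adjusted p = 0.272, adjusted p = 0.462 and adjusted p = 0.451 in that order. Their medians on slides 1 and 2 were -1.04 and -0.97, -1.49 and -0.83, -0.94 and -0.097, and -1.66 and -1.14.

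**Figure D3:**
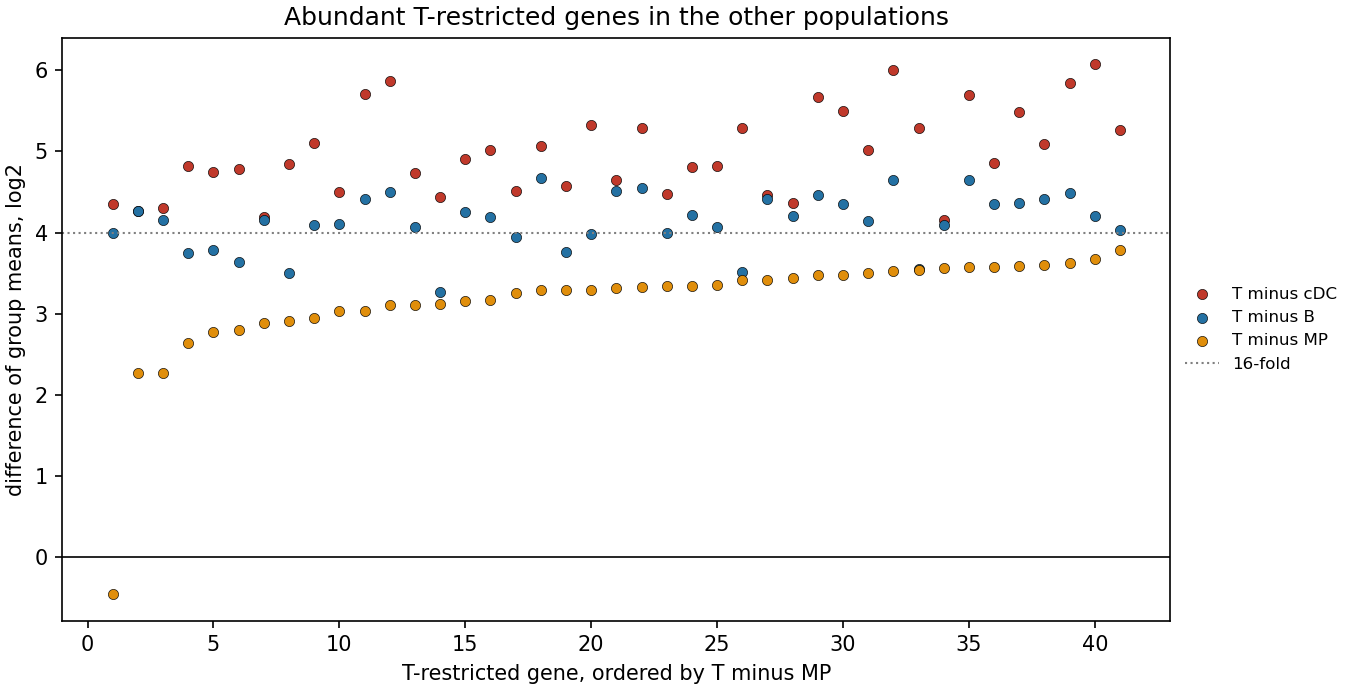
Difference of population means (log2 units) between T cells and each other population for 41 genes abundant in and restricted to T cells, 1 point per gene and population, ordered by T minus MP, with a dotted line at 16-fold. The genes were chosen without the MP arrays, and the medians are 3.32 for T minus MP, 4.15 for T minus B and 4.86 for T minus cDC.

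The other lists that passed camera in this comparison had lower medians in cDC. Chemokine and cytokine receptors had 6 higher and 22 lower of 45 (median -0.43, adjusted p = 0.00206). CSF3R, the receptor of the granulocyte growth factor, was at -7.45 ± 0.50 and IL1R1, the interleukin-1 receptor, at -5.68 ± 0.32. Chemokines and cytokines had 2 higher and 14 lower of 35 (median -0.60, or -0.43 with members below background at their bound, adjusted p = 0.0107). The list of red pulp macrophages and iron handling had 1 higher and 10 lower of 18 (median -0.60, adjusted p = 0.0107). The plasmacytoid dendritic cell list had 2 higher and 9 lower of 14 (median -0.81, adjusted p = 0.0315). Antigen receptor signalling had 7 higher and 14 lower of 30 (median -0.24, adjusted p = 0.0482, 0.0614 with slide and 0.0659 with the replicate number as a block). Adjusted over the list alone, the receptors had 6 higher and 23 lower, the cytokines 2 and 14, the red pulp list 2 and 10, the plasmacytoid list 2 and 9 and the signalling list 7 and 14. Each of these 5 lists had adjusted p = 0.272 with an estimated correlation. Their medians on slides 1 and 2 were -0.47 and -0.40, -0.85 and -0.65, -0.45 and -0.83, -0.87 and -0.76, and -0.31 and -0.18.

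Lists that did not pass camera between cDC and MP had the following counts of members higher and lower in cDC. The mature or migrating dendritic cell list had 2 and 10 of 24 (median -0.15, adjusted p = 0.0547) and the dendritic cell transcription factors 10 and 9 of 26 (median 0.15, adjusted p = 0.726), with a mean of -0.38. The interferon-stimulated genes had 7 and 6 of 33 (median 0.082, adjusted p = 0.731). The B-cell list had 9 and 12 of 31 (median -0.13, adjusted p = 0.448), the plasma cell list 4 and 1 of 10 (median 0.17, adjusted p = 0.306) and the erythroid list 0 and 2 of 21 (median -0.44, adjusted p = 0.115). MHC class I presentation had 1 and 2 of 13 (median -0.047, adjusted p = 0.466), actin and migration 9 and 11 of 36 (median -0.0065, adjusted p = 0.306) and the early response genes that rise during tissue digestion 3 and 6 of 28 (median -0.07, adjusted p = 0.448). Cytosolic ribosomal proteins had 2 and 3 of 63 (median -0.076, adjusted p = 0.072), glycolysis 2 and 5 of 25 (median -0.16, adjusted p = 0.115) and cholesterol synthesis 6 and 2 of 20 (median 0.17, adjusted p = 0.706). Adjusted over the list alone, in the same order, the counts were 3 and 10, 11 and 9, 7 and 6, 9 and 12, 4 and 1, 0 and 2, 1 and 2, 10 and 12, 3 and 5, 0 and 0, 1 and 4, 6 and 2. With an estimated correlation their adjusted p lay between 0.489 and 0.873.

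In all, 5860 of the 11539 genes were called between cDC and MP, 3418 higher and 2442 lower in cDC, of which 2230 differed at least 2-fold (872 higher and 1358 lower). With normexp background correction the balance turned, to 3445 higher and 3588 lower. The genes furthest above MP included LGALS2, a galectin, at 4.39 ± 0.41, CPM, a membrane carboxypeptidase, at 3.99 ± 0.40, and KCNJ5, a potassium channel above background on 3 MP arrays, at 4.12 ± 0.29. Those furthest below included DMBT1, a scavenger receptor protein, at -8.96 ± 0.50, AVD, avidin, at -8.77 ± 0.66, ACOD1 (listed as IRG1), which makes itaconate, at -7.83 ± 0.60, and VCAN, versican, at -7.83 ± 0.53. VNN2 (listed as VNN1), a pantetheinase, and FAP, a serine protease, were at least 185-fold and 194-fold lower in cDC. With slide as a block 6417 genes were called, with slide 1 alone 3663 and with slide 2 alone 3593. Camera called 18 of the 32 lists (3 higher and 15 lower in cDC), and with an estimated correlation it called 0, with 3 at an unadjusted p under 0.05.

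**Figure D4:**
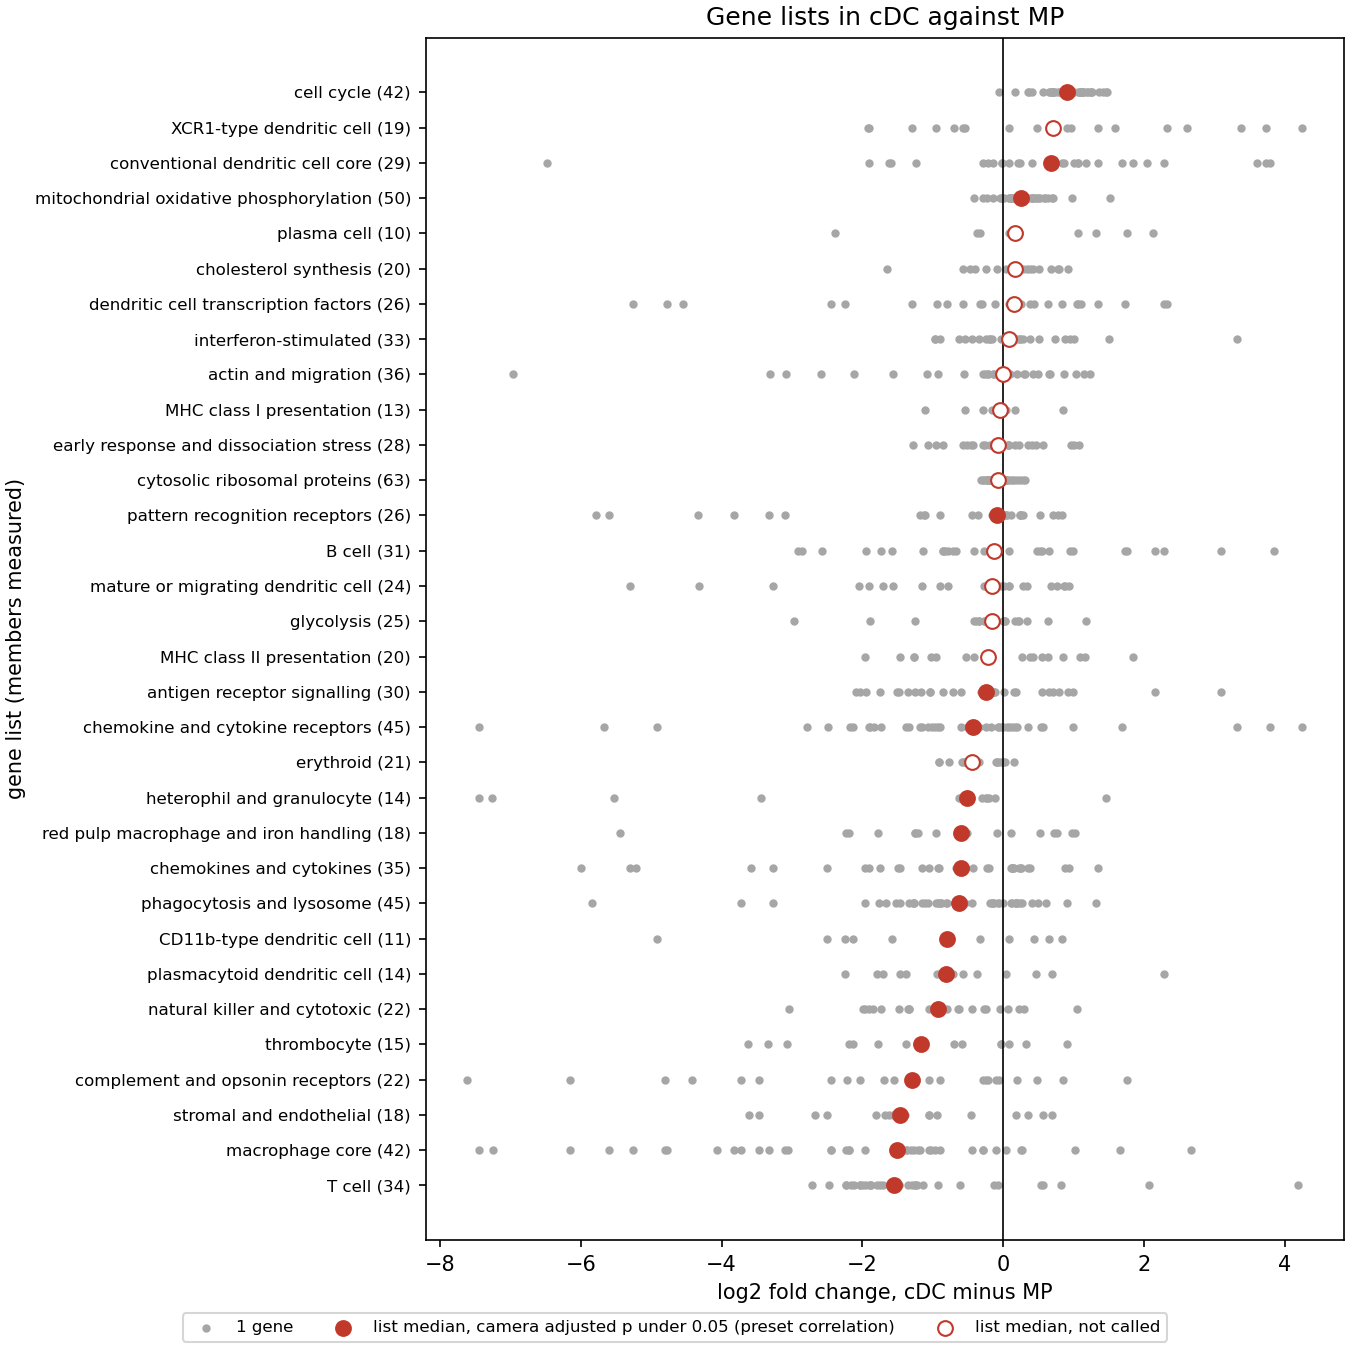
Log2 fold change of cDC minus MP for the members of each gene list (grey points, 1 per gene) and their median (filled red where camera with a preset correlation gave an adjusted p under 0.05, open otherwise), with the number of measured members in parentheses. The cell cycle list has the highest median, 0.90, and the T-cell list the lowest, -1.56; with a correlation estimated per list 0 lists passed.

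Against B cells (n = 4 against 3), several genes known from dendritic cells were again higher in cDC. XCR1 was higher by 7.70 ± 0.37 and CADM1 by 7.69 ± 0.41 (adjusted p = 1.42e-09 and 3.59e-09), FLT3 by 4.01 ± 0.52, ZBTB46 by 2.47 ± 0.25, IRF8 by 2.35 ± 0.22 and BATF3 by 2.12 ± 0.15. CSF1R, a member of the macrophage core list, was also higher in cDC, by 4.12 ± 0.46 (chromosome 13, 13373512 to 13373571). PAX5 and EBF1, the transcription factors that fix B-cell identity, were at least 142-fold and 123-fold lower in cDC (adjusted p = 6.03e-09 and 6.19e-09). MMP7, a matrix protease, was at least 389-fold lower, and the near-identical amylases AMY1A and AMY2A were at -7.74 ± 0.35 and -8.29 ± 0.47. TLR3 and TLR4 were lower in cDC, at -0.86 ± 0.28 and -1.06 ± 0.33 (adjusted p = 0.0189 and 0.0134). Both calls ended on slide 2 alone (-0.25 for TLR3 and -0.96 for TLR4) and without B replicate 1 (-0.54 and -0.94), and that of TLR3 also without cDC replicate 1 (-0.72).

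Of the XCR1-type list, 14 of 19 members were higher in cDC than in B cells, 4 lower and 1 not called (as adjusted over the list alone), and PLEKHA5 was at 6.56 ± 0.21. The median was 1.64 relative to the median gene (1.51 and 1.49 in all on slides 1 and 2), with adjusted p = 0.000477 and adjusted p = 0.275 with an estimated correlation. Of the B-cell list, 21 of 31 were lower, 6 higher and 4 not called (as adjusted over the list alone). VPREB3, a surrogate light chain, was at -6.29 ± 0.24 and TNFRSF13C, the BAFF receptor, above background on 1 cDC array, at -6.66 ± 0.34. Its median was -1.76 relative to the median gene (-2.08 and -1.63 on the slides), adjusted p = 0.000662 and adjusted p = 0.339 with an estimated correlation. Antigen receptor signalling was lower for 20 of 30, higher for 6 and not called for 4 (21 and 6 adjusted over the list alone). VAV2, an exchange factor, was at -5.43 ± 0.34 and NFATC1, a transcription factor, at -4.07 ± 0.17. This list had a median of -0.61 relative to the median gene (-0.79 and -0.64 on the slides), adjusted p = 0.0069 and adjusted p = 0.275 with an estimated correlation. Interferon-stimulated genes were higher for 20 of 33, lower for 5 and not called for 8 (as adjusted over the list alone). GBP, a guanylate-binding protein, was at 4.72 ± 0.34 and IFIT5 at 3.09 ± 0.17. The interferon list had a median of 0.72 relative to the median gene (0.65 and 0.57 on the slides), adjusted p = 0.000662 and adjusted p = 0.339 with an estimated correlation. MHC class II presentation was higher for 12 of 20, lower for 4 and not called for 4 (as adjusted over the list alone). BLB1 was at 2.21 ± 0.30 and CTSB, a cathepsin, at 1.47 ± 0.18. The class II list had a median of 0.86 relative to the median gene (0.61 and 0.79 on the slides), adjusted p = 0.0126 and adjusted p = 0.469 with an estimated correlation.

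Cytosolic ribosomal proteins were lower in cDC than in B cells for 61 of 63 members, higher for 0 and not called for 2 (62 lower adjusted over the list alone). RPL22 was at -1.18 ± 0.10 and RPL12 at -1.16 ± 0.086. Their median was -0.72 relative to the median gene (-0.78 and -0.93 in all on slides 1 and 2), adjusted p = 1.01e-15 in camera and adjusted p = 0.388 with an estimated correlation. The T-cell list was also lower in cDC than in B cells, for 24 of 34 members against 3 higher (as adjusted over the list alone; median -0.96 relative to the median gene, -1.53 and -0.27 on the slides). It passed camera (adjusted p = 0.00586) but not on slide 2 alone (adjusted p = 0.157), and had adjusted p = 0.594 with an estimated correlation. In all, 6690 genes were called, 2891 higher and 3799 lower in cDC, of which 3119 differed at least 2-fold (1590 higher and 1529 lower). With slide as a block 7184 genes were called, on slide 1 alone 5452 and on slide 2 alone, with 1 B array, 3831. Camera called 15 of the 32 lists (11 higher and 4 lower in cDC), with the dendritic cell core (15 higher and 7 lower of 29), lysosome (31 and 3 of 45) and respiratory chain (27 and 0 of 50) lists among the higher. Also higher were the heterophil and granulocyte list (9 and 1 of 14, median 2.92 relative to the median gene, adjusted p = 0.0149) and the macrophage core (19 and 6 of 42, median 0.67, adjusted p = 0.0149). With an estimated correlation it called 0, with 4 at an unadjusted p under 0.05.

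Against T cells (n = 4 against 4), FLT3 was higher in cDC by 6.46 ± 0.49, XCR1 by 6.38 ± 0.34, CADM1 by 6.59 ± 0.38, CSF1R by 5.25 ± 0.43 and IRF8 by 4.92 ± 0.21 (adjusted p = 5e-08, 1.92e-09, 3.41e-09, 1.1e-07 and 2.48e-10). ZNF366, a zinc finger protein, rose by 6.95 ± 0.34, and CD86, a costimulatory ligand above background on 3 T arrays, by 6.68 ± 0.39. ZBTB46 was higher by 2.64 ± 0.23 and BATF3 by 1.27 ± 0.14, while ID2 differed by -0.28 ± 0.15 (adjusted p = 0.114, not called). ID2 was called lower in cDC with quantile normalization (-0.45), the authors' values (-0.50) and array weights (-0.32), and was at 0.16 with the mean of its probes. CD8BP, a CD8 beta chain, TRAT1, a T-cell receptor adaptor, and UBASH3A, a regulator of T-cell signalling, were lower in cDC, at -6.003 ± 0.44, -5.85 ± 0.38 and -5.69 ± 0.34. BCL11B, a transcription factor of T cells, was at -5.49 ± 0.36 and TLR3 at -1.94 ± 0.26 (adjusted p = 1.22e-08 and 1.74e-05).

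The T-cell list was lower in cDC for 32 of 34 members, higher for 2 and not called for 0 (as adjusted over the list alone). Its median was -4.55 relative to the median gene (-4.90 and -4.35 in all on slides 1 and 2), with adjusted p = 4.72e-11 in camera and adjusted p = 0.313 with an estimated correlation. The conventional dendritic cell core was higher for 19 of 29, lower for 5 and not called for 5 (as adjusted over the list alone). ASS1, an enzyme of arginine synthesis, was at 5.71 ± 0.38. Its median was 1.85 relative to the median gene (1.59 and 1.91 on the slides), adjusted p = 0.00019 and adjusted p = 0.225 with an estimated correlation. MHC class II presentation was higher for 15 of 20, lower for 4 and not called for 1 (as adjusted over the list alone). CIITA was at 5.58 ± 0.16, BLB1 at 5.12 ± 0.28 and DMB2 (listed as B-MA2), which loads peptides, at 4.55 ± 0.18. Its median was 2.34 relative to the median gene (2.37 and 2.098 on the slides), adjusted p = 2.14e-05 and adjusted p = 0.313 with an estimated correlation. Cytosolic ribosomal proteins were lower for 62 of 63 and higher for 1 (as adjusted over the list alone), with RPL22 at -1.39 ± 0.096 and RPS6 at -1.19 ± 0.077. They had a median of -0.79 relative to the median gene (-0.83 and -0.91 on the slides), adjusted p = 1.45e-13 and adjusted p = 0.349 with an estimated correlation. Cell cycle genes were higher in cDC for 28 of 42 and lower for 4 (30 and 4 adjusted over the list alone). Their median was 0.60 relative to the median gene (0.38 and 0.57 on the slides), with adjusted p = 0.000791 and adjusted p = 0.48 with an estimated correlation. In all, 7503 genes were called, 3286 higher and 4217 lower in cDC, of which 3729 differed at least 2-fold (1883 and 1846). With slide as a block 7933 were called, on slide 1 alone 6269 and on slide 2 alone 5665. Camera called 14 of the 32 lists (12 higher and 2 lower), and 0 with an estimated correlation, with 3 at an unadjusted p under 0.05.

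The macrophage population stood apart from B cells (n = 4 against 3) by AVD at 8.02 ± 0.72, FN1 at 7.45 ± 0.48, IL1B, the cytokine interleukin-1 beta, at 7.41 ± 0.55, and MMP9, a matrix protease, at 7.37 ± 0.56. CSF1R was higher by 5.08 ± 0.46 (adjusted p = 5.38e-07), while CADM1 and XCR1 were higher by 5.08 ± 0.41 and 3.46 ± 0.37. FLT3 and IRF8 differed by 0.23 ± 0.52 and 0.019 ± 0.22 (adjusted p = 0.729 and 0.948, not called), with IRF8 at -0.034 with slide as a block and FLT3 at -0.000234 without B replicate 2. VPREB3 and the B-cell factor PAX5, above background on 3 MP arrays, were lower in MP, at -5.50 ± 0.24 and -5.56 ± 0.47. Of the macrophage core list, 35 of 42 were higher in MP, 2 lower and 5 not called (as adjusted over the list alone). C1QC was at 7.03 ± 0.51 and CSF3R at 7.13 ± 0.54. Its median was 2.96 relative to the median gene (2.46 and 2.87 in all on slides 1 and 2), or 2.57 against 2.77 in all with members below background at their bound. It had adjusted p = 1.21e-12 and adjusted p = 0.0997 with an estimated correlation. Cell cycle genes were lower in MP for 37 of 42 and higher for 0 (as adjusted over the list alone), with TYMS and MCM6, which serve DNA synthesis, at -1.71 ± 0.14 and -1.64 ± 0.17. These had a median of -0.62 relative to the median gene (-0.75 and -0.93 on the slides), adjusted p = 4.81e-06 and adjusted p = 0.27 with an estimated correlation.

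Members of lists of other cells were also higher in MP than in B cells, among them 12 of 14 heterophil and granulocyte genes (median 4.83 relative to the median gene, 5.06 and 3.63 in all on slides 1 and 2). That list shares CSF3R with the macrophage core list. EXFABP was at 6.90 ± 0.49 and CATH2, a cathelicidin listed as CATHL2, at 6.25 ± 0.94. They had adjusted p = 4.33e-05 and adjusted p = 0.197 with an estimated correlation, with 1 lower and the same counts adjusted over the list alone. Thrombocyte genes were higher for 10 of 15 (adjusted p = 0.0063), stromal and endothelial genes for 13 of 18 (adjusted p = 0.000594), natural killer and cytotoxic genes for 10 of 22 (adjusted p = 0.00339) and erythroid genes for 10 of 21 (adjusted p = 0.0188). With an estimated correlation these had adjusted p = 0.206, 0.25, 0.197 and 0.534. Adjusted over the list alone, 10, 14, 10 and 10 of their members were higher and 2, 1, 2 and 4 lower. Their medians on slides 1 and 2 were 0.81 and 1.08, 2.25 and 2.43, 0.64 and 1.47, and 0.99 and 2.16. The T-cell list had 11 of 34 higher and 8 lower in MP than in B cells, with adjusted p = 0.294 and adjusted p = 0.862 with an estimated correlation. In all, 7355 genes were called, 2848 higher and 4507 lower in MP, of which 3405 differed at least 2-fold (1825 and 1580). With slide as a block 7789 were called, on slide 1 alone 6334 and on slide 2 alone, with 1 B array, 4732. Camera called 23 of the 32 lists (20 higher and 3 lower), and 0 with an estimated correlation, with 7 at an unadjusted p under 0.05.

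Against T cells (n = 4 against 4), MP had more C1QC and C1QA, chains of C1q, by 7.35 ± 0.48 and 7.13 ± 0.47, more TLR4 by 6.47 ± 0.30 and more CSF1R by 6.21 ± 0.43 (adjusted p = 1.43e-08, 1.74e-08, 8.04e-10 and 2.42e-08). CD3E was lower in MP than in T cells, at -2.90 ± 0.28, as were BCL11B, at -3.59 ± 0.36, and ZAP70, a kinase of T-cell receptor signalling, at -3.98 ± 0.29. FLT3 and IRF8 were higher in MP by 2.67 ± 0.49 and 2.58 ± 0.21. Of the phagocytosis and lysosome list, 41 of 45 were higher in MP, 2 lower and 2 not called (as adjusted over the list alone). The cathepsins CTSV (listed as CTSL2) and CTSK were at 5.60 ± 0.37 and 4.76 ± 0.20. Its median was 2.26 relative to the median gene (2.07 and 2.00 in all on slides 1 and 2), adjusted p = 4.72e-16 and adjusted p = 0.0598 with an estimated correlation. The macrophage core was higher for 38 of 42 and lower for 2 (as adjusted over the list alone). Its median was 4.38 relative to the median gene (4.50 and 3.81 on the slides), with adjusted p = 1.38e-14 and adjusted p = 0.0643 with an estimated correlation. Lists of other cells were higher in MP than in T cells as well, with 12 of 15 thrombocyte genes (adjusted p = 7.4e-05), 15 of 18 stromal and endothelial genes (adjusted p = 0.000147) and 12 of 14 heterophil and granulocyte genes (2 lower, adjusted p = 0.00239). With an estimated correlation these had adjusted p = 0.104, 0.198 and 0.27. The T-cell list was lower in MP for 32 of 34 and higher for 1 (as adjusted over the list alone). Its median was -2.90 relative to the median gene (-3.35 and -2.85 on the slides), with adjusted p = 1.49e-08 and adjusted p = 0.198 with an estimated correlation. Cytosolic ribosomal proteins were lower in MP for 62 of 63 members against T cells and 61 of 63 against B cells, with medians of -0.56 and -0.59 relative to the median gene (-0.87 and -0.72, and -0.83 and -0.75, in all on the slides). Adjusted over the list alone, 62 and 61 were lower. Their adjusted p = 4.61e-11 and 1.93e-12, and adjusted p = 0.278 and 0.252 with an estimated correlation. In all, 8159 genes were called, 3168 higher and 4991 lower in MP, of which 3914 differed at least 2-fold (2039 and 1875). With slide as a block 8581 were called, on slide 1 alone 7068 and on slide 2 alone 6237. Camera called 22 of the 32 lists (19 higher and 3 lower), and 0 with an estimated correlation, with 11 at an unadjusted p under 0.05.

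Between the lymphocytes (n = 3 B against 4 T), PAX5 was higher in B cells by 6.11 ± 0.47 and EBF1, above background on 3 T arrays, by 5.78 ± 0.41 (adjusted p = 1.91e-07 and 8.61e-08). CIITA rose by 4.28 ± 0.17. Lower in B than in T cells were CD3E at -3.51 ± 0.30, BCL11B at -4.37 ± 0.39, TRAT1 at -4.48 ± 0.41 and XCL1, the ligand of XCR1, at -4.55 ± 0.55 (adjusted p = 5.14e-07, 7e-07, 1.06e-06 and 1.45e-05). Of the B-cell list, 23 of 31 were higher in B cells, 2 lower and 6 not called (24 and 2 adjusted over the list alone). Its median was 2.84 (3.20 and 2.41 on slides 1 and 2, 2.87 with slide as a block), with adjusted p = 1.32e-11 and adjusted p = 0.0836 with an estimated correlation. Of the T-cell list, 30 of 34 were lower in B cells and 1 higher (as adjusted over the list alone). Its median was -3.51 (-3.36 and -3.83 on the slides), with adjusted p = 1.42e-15 and adjusted p = 0.234 with an estimated correlation. MHC class II presentation was higher in B cells for 15 of 20 and lower for 1 (as adjusted over the list alone). Its median was 1.61 (1.82 and 1.47 on the slides), with adjusted p = 2.15e-07 and adjusted p = 0.234 with an estimated correlation. Natural killer and cytotoxic genes were lower in B cells for 15 of 22 and higher for 3 (as adjusted over the list alone). Their median was -2.03 (-2.06 and -2.002 on the slides), with adjusted p = 0.00195 and adjusted p = 0.234 with an estimated correlation. Of the 63 cytosolic ribosomal proteins limma called 0 (median -0.0084, camera adjusted p = 0.858), whereas the authors' values gave a median of -0.35 (camera adjusted p = 6.53e-09). In all, 4426 genes were called, 2128 higher and 2298 lower in B cells, of which 2114 differed at least 2-fold (1102 and 1012). With slide as a block 4845 were called, on slide 1 alone 3140 and on slide 2 alone, with 1 B array, 2139. Camera called 13 of the 32 lists (11 higher and 2 lower), 0 with an estimated correlation and 1 with slide as a block added, with 5 at an unadjusted p under 0.05 under each.

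Genes at least 2-fold higher in 1 population than in each of the other 3 numbered 423 for cDC, 639 for MP, 316 for B cells and 529 for T cells. The cDC set was headed by SMOC2, LGALS2, XCR1 and KCNJ5, with a smallest log2 fold change of 4.39 for LGALS2 and 4.25 for XCR1. The MP set was headed by VNN2, AVD, DMBT1 and ACOD1, the B-cell set by PAX5, AMY2A and EBF1, and the T-cell set included ZAP70 and PRF1, perforin. Genes higher in cDC and MP than in both lymphocytes numbered 756, where lists drawn independently would share 147. TLR15, a Toll-like receptor of birds, was at 3.69 ± 0.11 in cDC and 3.67 ± 0.57 in MP (SD, n = 4 each) against -2.34 ± 0.25 in B cells (n = 3) and -2.79 ± 1.09 in T cells (n = 4). MERTK, a receptor for dying cells, was at 3.73 ± 0.094 and 4.02 ± 0.24 against -1.44 ± 0.49 and -2.02 ± 0.71, and the near-identical chemokines IL8L1 and IL8L2 and the arginine synthesis enzyme ASS1 were in the same set. Higher in cDC and B cells than in the others were 67 genes (20.7 by independent lists), including BCL11A, a transcription factor, at 5.13 ± 0.098 in cDC and 6.11 ± 0.044 in B cells. Higher in cDC and T cells were 44 (25.8 by independent lists), including the transcription factors MYCN and SATB1, at 1.54 ± 0.21 and 0.90 ± 0.12 in cDC. The MP and T cells shared 123 (44.6 by independent lists), MP and B cells 95 (28.1) and B and T cells 464 (100.1). With normexp background correction the sets shared by cDC with MP, B and T cells numbered 486, 30 and 22. Sets shared by a pair were tested against the same other arrays, which were too few to divide, so part of each excess may come from those shared arrays.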

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

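The tests for T cells among the MP, for array scaling of each pattern, for cycling B cells and for a difference between slides were chosen after the result was seen. A sample is listed here when its gap to the nearest of the 4 arrays of its population, divided by the population's range, exceeded Dixon's 95% critical value. Chance sets apart about 1 in 20 groups, and 22 of 432 groups stood out (4 of the list scores and 18 of the gene levels, none of the array measures).

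T-cell transcripts were higher in MP than in cDC. Array scaling is argued against, since the T-cell list's median stayed at -1.22 or further from 0 with quantile normalization, normexp and the authors' values. Of 41 genes abundant in T cells and restricted to them, chosen without the MP arrays, 0% were at least 16-fold lower in MP than in T cells (median 3.32 log2 lower), with CD3E at 5.25, CD3D at 7.46 and CD247 at 3.65 in MP. The 16-fold limit was set after the result was seen and lies above the highest value, 3.785. A lower limit would give a larger share, so the 0% decides nothing by itself. T cells among the sorted MP remain a candidate source, and the labels give no exclusion of CD3 in the KUL01 sort. Transcription of such genes by the MP themselves stays open, since the SD between the 41 genes, 0.676, lay between the bounds set for it, although it rests on SNTB1, at 0.46 in MP minus T (not called) and -4.36 in cDC minus T, with the other 40 genes at 2.27 to 3.785 in T minus MP and an SD of 0.353 (bootstrap interval 0.249 to 0.438), under the lower bound, which decides nothing by itself as SNTB1 was left out for its own value. Of the 34 measured members of the T-cell list, 10 stand in another list and 15 are among the 41 genes. The same 41 genes were a median of 4.15 log2 lower in B than in T cells. Far lower levels in cDC and in B cells were a condition of their choice, so only the MP level was free to vary.

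Of 42 cell cycle genes, 40 were higher in cDC than in MP. Array scaling does not account for it, as the median was 0.864 at the least with quantile normalization, normexp and the authors' values. A general difference of transcripts of this abundance is argued against as well, since the list's median stood at percentile 100 of 10000 random lists matched on mean expression, whose medians lay between -0.41 and 0.42. Cycling B cells among the cDC are argued against by 26 abundant B-restricted genes, which had a median of -4.80 in cDC minus B. More cycling cells among cDC or fewer among MP may each be stated as a hypothesis found and tested on the same data, since against B cells cDC had 8 of 42 higher and 7 lower (median 0.16, adjusted p = 0.266) and MP 37 lower, while against T cells cDC had 28 higher and MP 27 lower.

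Ribosomal protein transcripts were lower in cDC and MP than in B and T cells, by a median of -0.83. Array scaling alone does not account for it, with a median of -0.669 nearest to 0 under quantile normalization, normexp and the authors' values. The authors' values also set this list lower in B than in T cells, as given above, so the size of the difference depends on the processing. A general compression of bright probes is argued against by percentile 0 among 10000 random lists matched on mean expression (medians -0.40 to 0.32). The matching used broad classes of expression, so compression confined to the very brightest probes was not tested. Both slides held every population, so an offset between slides largely cancels by design. The medians of -0.83 on slide 1 and -0.818 on slide 2 show only that the pattern stood on each slide. A biological difference between phagocytes and lymphocytes may be stated as a hypothesis only, found and tested on the same data.

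In cDC replicate 1, T-cell genes stood below the other cDC arrays. CD3E was at 2.31 there (3.58 to 3.74 in the others), CD247 at 0.517 (1.90 to 2.103), BCL11B at -1.70 (-0.17 to 0.098), CD8BP at -0.673 (1.31 to 1.33), TRA@ at 0.462 (2.40 to 2.47) and PRF1 at -6.98 (-5.24 to -4.89). In the other cDC arrays, CTSK was at 0.427 in replicate 2 (0.85 to 0.91), TLR1B at -3.14 in replicate 3 (-2.82 to -2.77) and XCR1 at 4.21 in replicate 3 (3.82 to 3.84).

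In MP replicate 3, the array with the lowest 75th percentile, 337, the heterophil and granulocyte score was 1.89 (2.39 to 2.45 in the others) and the early response score -0.297 (0.22 to 0.23). The same array had MYCN at -1.84 (-1.45 to -1.38), VCAN at 1.75 (4.13 to 4.595) and S100A12 at 3.14 (4.48 to 4.542). In MP replicate 1, the cell cycle score was -0.407 (-0.63 to -0.60), the antigen receptor signalling score -0.349 (-0.25 to -0.24) and XCL1 1.92 (3.26 to 3.53). In MP replicate 2, NFATC1 was at -1.81 (-1.33 to -1.26) and VAV2 at -2.67 (-1.79 to -1.65). In T cells, CD36 was at -2.53 in replicate 3 (-3.57 to -3.50), MCM6 at 2.00 in replicate 2 (1.33 to 1.36) and RPS6 at 7.84 in replicate 3 (7.75 to 7.77).

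Outside the gene comparisons, 798 probes are named by a human or mouse transcript. Of these, 91 were well above background on all 15 arrays and 181 on at least 3. Tested among the unnamed probes, 4 of them were specific to cDC and 5 to MP by limma at the 2-fold threshold.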

How the results depend on the processing

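Camera with an estimated correlation and slide as a block was added after the data were seen, and the other settings were planned. Of 503 printed or rule-named fold changes, between 485 and 501 kept their direction and side of the threshold under each setting that gave all 503, and 502 of 502 did with the stricter filter. With each array left out in turn, 7492 of 7545 did. The cause of the changes listed here was not tested, except that a slide alone has fewer arrays.

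The counts of genes moved by over 1.5 times on the slides alone. Between cDC and MP, slide 1 gave 3663 and slide 2 gave 3593, and slide 2 gave 3831 for cDC against B, 4732 for MP against B and 2139 for B against T, where 1 B array is assumed to vary like the others. With normexp the sets shared by cDC numbered 486 with MP, 30 with B and 22 with T cells, and the share of called genes higher in cDC than in MP went from 58.3% to 49.0%. With the replicate number as a block, which contains the slide, 6398, 7096, 7946, 7690, 8557 and 4664 genes were called for cDC against MP, B and T, MP against B and T, and B against T. Camera then called 15 lists for cDC against MP and 12 for B against T. In these 2 comparisons, where the numbers were taken to pair the samples, the block changed no call printed in the report besides the 3 lists named there. The pairing stays uncertain, as cDC replicate 4 correlated by 0.1381 with MP replicate 4 and by 0.2531 with MP replicate 3. In the other comparisons too, not every sample correlated best with its own number: for cDC and B, cDC and T, MP and B and MP and T the mean was 0.0436, 0.109, 0.0902 and 0.187, against 0.233, 0.266, 0.171 and 0.125 for other numbers on the slide. With an estimated correlation camera called 0 lists in each comparison, with 3, 4, 3, 7, 11 and 5 at an unadjusted p under 0.05 in the same order. Adding slide as a block, it called 0 in each apart from 1 for B against T, with 2, 4, 2, 5, 10 and 5 unadjusted.

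Profile distances moved by more than their spread. With normexp they were 0.0564 for cDC to MP, 0.0816 for cDC to B, 0.107 for cDC to T, 0.0968 for MP to B, 0.116 for MP to T and 0.0548 for B to T. Without a filter they were 0.0422, 0.061, 0.0741, 0.0701, 0.0788 and 0.0441 in that order, and with the mean of probes 0.0817, 0.112, 0.144, 0.133, 0.157 and 0.0787. The authors' values gave 0.0602 for cDC to MP, 0.0864 for cDC to B and 0.059 for B to T, and the stricter filter 0.073, 0.104, 0.133 for cDC to MP, B and T and 0.0714 for B to T.

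The fold changes that turned in sign belonged to genes not called. BLB2 in cDC minus MP was 0.0905 with quantile normalization, 0.028 with the authors' values and 0.67 with the mean of probes, and ID2 in cDC minus T was 0.16 with the mean of probes. IRF8 in MP minus B was -0.034 with slide as a block, -0.039 on slide 2, -0.025 with the replicate block, -0.13 without B replicate 2 and -0.022 without MP replicate 4, up to 0.13 without B replicate 1. In MP minus B, FLT3 ranged from -0.000234 without B replicate 2 to 0.60 without B replicate 1, and ID2 from -0.31 without B replicate 1 to 0.036 without B replicate 2. CD3D in MP minus B was -0.057 on slide 1.

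Leaving out each array in turn gave 5318 to 5907 genes called for cDC against MP, 5912 to 6884 for cDC against B, 7151 to 7681 for cDC against T, 6744 to 7376 for MP against B, 7768 to 8141 for MP against T and 3758 to 4618 for B against T. Specific genes ranged over 407 to 431 for cDC, 604 to 652 for MP, 286 to 336 for B and 511 to 544 for T, and genes shared by cDC over 722 to 763 with MP, 63 to 72 with B and 41 to 50 with T. Lists called ranged over 16 to 20, 12 to 17, 14 to 16, 21 to 23, 22 to 24 and 10 to 16 in the order of the comparisons. Distances ranged over 0.0663 to 0.0689, 0.0903 to 0.0979, 0.117 to 0.124, 0.106 to 0.116, 0.125 to 0.134 and 0.0643 to 0.0669. Signal over background limits the dim genes: 68.5 to 77.7% of probes were well above it, and with members below it at their bound, list medians moved by at most 0.803 (the stromal and endothelial list in MP minus T), with 0 changes of sign.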

Other observations

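TM7SF4, a fusion receptor of dendritic cells and osteoclasts, was at least 51.5-fold lower in cDC than in MP (adjusted p = 1.85e-06), and the glutathione transferase GSTA3 stood at -7.79 (1.30e-09). The decoy receptor IL1R2 and the granulocyte protein S100A12 were also lower in cDC, at -4.92 (1.54e-06) and -3.44 (4.81e-06). NT5E, an ectonucleotidase, was at least 109-fold higher in cDC than in B cells (6.35e-08), and SMPDL3A at least 110-fold higher in MP than in T cells (1.02e-08). The IL-33 receptor gene IL1RL1 was at least 19.1-fold lower in B than in T cells (2.05e-06), whereas CHIR-B4, an immunoglobulin-like receptor, was higher in B cells at 4.42 (6.90e-09).

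The number of genes called was set against every split of the 7 or 8 arrays of a comparison, 35 each. The real split gave the most genes in each comparison. These splits ignore slide and number, so chance was excluded only when both are left aside. Between populations, residuals correlated by a mean of 0.165 on the same slide under other numbers and of -0.166 across slides. The real split, 1 of 35, gave 5860 for cDC against MP (highest other split 1), 6690 for cDC against B (3745), 7503 for cDC against T (1), 7355 for MP against B (5062), 8159 for MP against T (1) and 4426 for B against T (2186). In the comparisons with B cells, some splits set 3 arrays of the other population against its remaining array and all 3 B arrays. Such splits nearly restore the real difference, so the highest other counts there are not a chance level. Splits that mix the populations unequally keep part of the real difference, so their list counts are not a chance level. They neither exclude chance nor show it for the lists called, where between 5 and 13 of the 35 splits gave as many. These were 5 splits for cDC against MP (real 18, highest other 20), 11 for cDC against B (15, 19), 13 for cDC against T (14, 19), 7 for MP against B (23, 25), 9 for MP against T (22, 25) and 8 for B against T (13, 20). The split that follows the slides gave 9, 2, 5, 3, 6 and 4 lists, below the real counts. The 8 splits that part all 4 numbered pairs of cDC and MP are too few for a share under 0.05, and the real one gave 5860 genes and 18 lists (highest other 0 and 18). The same holds for the 8 that part all 3 pairs of B and T cells, with 4426 genes and 13 lists (highest other 2186 and 20). Splits that part fewer pairs gave up to 20 lists for cDC against MP and 17 for B against T.

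Of 100 random splits of the 15 arrays into the 4 groups, the real one included, only the real one (1) gave sets as large. It gave 423 genes specific to cDC (highest other 1), 639 to MP (2), 316 to B (0) and 529 to T cells (0). It gave 756 genes shared by cDC and MP, 67 by cDC and B and 44 by cDC and T, with 0 as the highest other for each. The random splits mix sorted populations within a group and ignore slide and number. They thus show only that the populations differ, and cannot weigh the size of any of these 7 sets.

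Of the 123 genes at least 2-fold higher in both MP and T cells than in cDC and B cells, 60 were called higher in T cells than in MP. Without cDC replicate 1, the array with the lowest T-cell transcripts, CD3E in cDC minus MP was -1.61, and 5579 genes were called for cDC against MP.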
